A study of Rattus norvegicus with 6 samples.

How the data were processed

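Messenger RNA was sequenced from back skin of Sprague-Dawley rats in 6 libraries, 2 from untreated rats, 2 from rats with a gefitinib rash and 2 from rats with an afatinib rash. Per the labels, skin was flash frozen, RNA was extracted with Trizol, and TruSeq RNA libraries were made from 1 ug of total RNA. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used; the step each served, the genome build, the annotation release and the strand of counting are not given in the sources used here. The deposited count table holds whole read counts per gene, with no scaling. The deposited FPKM table holds, by the authors, the count divided by gene length and by a divisor for each library; that divisor was checked to equal the DESeq2 size factor times 19675160, so a scaling between libraries is built into it. Every column of both tables was assigned to a sample by the code in its title.

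The count table has 34225 loci, of which 1342 carry an identifier and coordinates but no gene name. These unnamed loci held 1.68% to 2.54% of the counts of a library, and they stayed in the library sizes and in the tests but were never named. Library totals ran from 17206456 to 22086673 counts. The labels name no molecular identifiers, so every interval on counts and every floor covers counting error only. A gene at 0 in all libraries of a group was set to a floor of 3 counts per library, and its fold is given as a bound. Where the reference group held 1 to 3 counts, the ratio of summed counts is given with its 95% exact interval.

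Genes were filtered with filterByExpr of edgeR at its defaults, which left 16398 loci holding 99.91% to 99.96% of each library's counts. Counts were scaled with TMM and fitted with the edgeR 4.0.16 quasi-likelihood model in R 4.3.3, with 1 term per group over all 6 libraries and 3 residual degrees of freedom. The 4 comparisons were gefitinib against untreated, afatinib against untreated, the mean of both inhibitors against untreated, and afatinib against gefitinib. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05 and no fold threshold. The SE of a log2 fold change was derived from its F statistic. CPM values are TMM-scaled and given as mean ± SD of 2 libraries.

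Before the data were examined, 35 gene lists were fixed, 18 for pathways and skin compartments and 17 for cell types. Of their 634 genes 591 were in the files and 532 were tested; the list of Y-linked genes and Xist had no tested member, which left 34 lists. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares the list with all other genes, and adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, which tests whether the genes of a list move on balance one way, the count of members past the test over all genes, and the count adjusted over the list alone. Some genes sit in more than 1 list: S100a8 and S100a9 are both stressed keratinocyte and neutrophil genes, Mmp8 and Mmp9 both protease and neutrophil genes, and Col14a1, Lum and Dcn both collagen and fibroblast genes.

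The genes to name were chosen by a rule. For each inhibitor against untreated, and for their mean, they were the 10 genes per direction with the largest log2 change among those that passed, with every treated library on the same side of both untreated libraries and a mean of at least 1 CPM in the higher group. For afatinib against gefitinib they were 5 per direction. Unnamed or predicted loci and ribosomal or tRNA genes were passed over, and at most 3 genes sharing leading letters were taken per direction; where too few passed, the set was filled by unadjusted p. From each list up to 4 members with the smallest p were added, and the drug targets Egfr, Erbb2, Erbb3 and Erbb4 were always included.

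Both inhibitor comparisons use the same untreated libraries, so the overlap of their calls was set beside 20 simulations in which no group differed and beside the overlap of independent lists. The gene test was also tested on simulated data of this size, with 5 simulations of 15998 genes of which 200 were changed. Of 4-fold changes it recovered 47.7% for gefitinib, 45.9% for afatinib and 64.4% for their mean; of 2-fold changes it recovered 2.19%, 0.938% and 3.75%. False calls made up 11.1%, 12.1% and 11.9% of the calls in these comparisons, above the nominal 5%, and for afatinib against gefitinib, where no gene was changed, 2 of 80086 tests were called. In the data themselves more than 200 genes passed against untreated, which changes the Benjamini-Hochberg cut-off. The rates of recovery and of false calls may therefore not carry over. A list raised by simulation was called in 5 of 5 runs, and 2 of 170 other lists were called. Genes were drawn independently of each other there, so these runs cannot test the preset correlation or the list calls that depend on it.

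The alternatives were size factors of the DESeq2 kind, library size only, 2 other filters on low counts, DESeq2 1.42.0, limma-voom, the deposited FPKM with limma, robust dispersions, only the groups compared, the replicate number as a block, other thresholds and leaving out each library in turn. A fit with the mean of the skeletal muscle list as a covariate was added after the data were seen. Relative to untreated skin, that mean in log2 was −2.71 to −0.606 in the treated libraries and 0.104 and −0.104 in the untreated ones. The covariate thus overlaps with treatment, and it adds a term to a fit with 3 residual degrees of freedom. A fall in calls with it therefore cannot tell muscle content from treatment. Protein family enrichment, also chosen after the data were seen, used the one-sided Fisher's exact test over the 13521 tested genes with an annotated family. The labels do not say that the libraries of a group come from separate animals; the p-values then measure only the spread between these samples, which may be technical. Sex is not given in the sources used here and was not used.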

Results

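The series holds RNA sequencing of back skin from Sprague-Dawley rats, an outbred laboratory strain, in 3 groups of 2 libraries. Untreated rats were set against rats in which an inhibitor of the epidermal growth factor receptor (EGFR) had brought on a rash. EGFR is a receptor tyrosine kinase that drives keratinocyte growth, and rash is a common side effect of blocking it. Gefitinib, a reversible EGFR inhibitor, was given by mouth at 80 mg/kg a day. Afatinib, which shares the anilinoquinazoline core of gefitinib but binds EGFR, ERBB2 and ERBB4 covalently, was given by mouth at 30 mg/kg a day. Dosing went on until the rash appeared, so the doses differ and the times may differ too.

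The untreated libraries held 20166522 and 22086673 counts, the gefitinib libraries 19772043 and 20560892, and the afatinib libraries 17206456 and 18619303. Between 18487 and 19913 genes had at least 1 count. Genes of contractile skeletal muscle took 20.7% (95% Wilson interval 20.7% to 20.7%) and 19.1% (19.1% to 19.1%) of the counts in the untreated libraries. They took 5.14% (5.13% to 5.15%) and 8.93% (8.92% to 8.94%) in the gefitinib libraries, 16.1% (16.1% to 16.1%) in afatinib replicate 1 and 5.65% (5.64% to 5.66%) in afatinib replicate 2. Genes of the hair follicle and hair shaft took 0.0122% (0.0118% to 0.0127%) and 0.036% (0.0352% to 0.0368%) in untreated skin. Their share was 1.13% (1.13% to 1.14%) and 0.698% (0.694% to 0.702%) with gefitinib, and 0.178% (0.176% to 0.18%) and 0.966% (0.962% to 0.971%) with afatinib. Collagen and matrix genes took 0.227% (0.225% to 0.229%) in gefitinib replicate 2, the lowest share of the 6 libraries.

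Across genes, which are not independent replicates, afatinib replicate 1 correlated with the untreated libraries at r = 0.935 and 0.939 and with afatinib replicate 2 at r = 0.925. The untreated pair correlated at r = 0.968 and the gefitinib pair at r = 0.963. The plot of gene lists shows the libraries one by one.

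**Figure D1:**
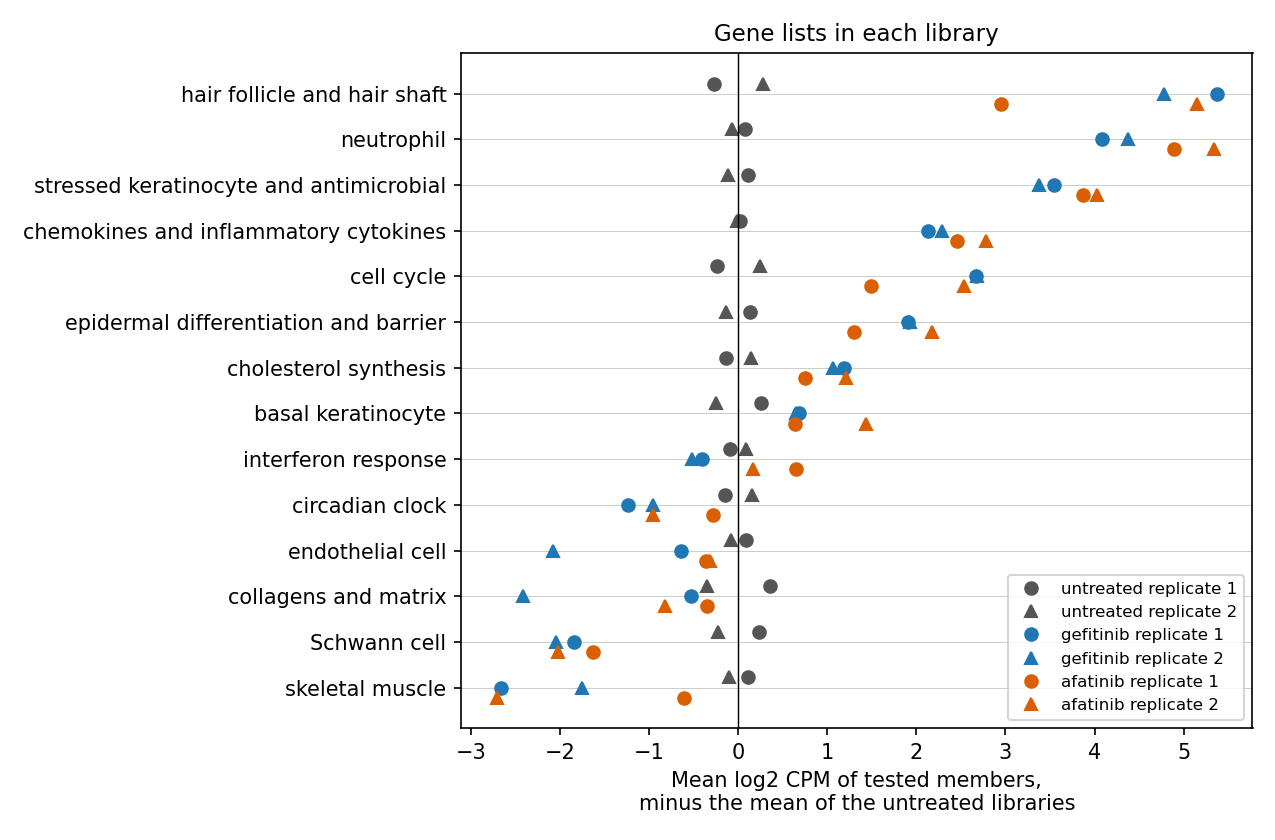
Mean log2 CPM of the tested members of 14 gene lists in each library, minus the mean of the untreated libraries; colours mark the groups and shapes the replicates. The hair list lies at 5.37 and 4.78 with gefitinib and at 2.95 and 5.15 with afatinib, and the Schwann cell list lies between −2.05 and −1.63 in the 4 treated libraries.

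Gefitinib against untreated asks how skin with a gefitinib rash differs from normal skin. Hair genes rose in both gefitinib libraries, among them Krt31, a keratin of the hair cortex, from 1.80 ± 0.00404 to 313 ± 173 CPM (mean ± SD, n = 2). Inflammatory and barrier genes rose with them: S100a9, a subunit of the neutrophil and keratinocyte protein calprotectin, went from 0.491 ± 0.283 to 476 ± 202 CPM (n = 2), and Tgm1, which cross-links the cornified envelope, from 1.80 ± 0.495 to 34.2 ± 5.21 CPM (n = 2). Mki67, a marker of dividing cells, went from 24.2 ± 1.43 to 236 ± 24.5 CPM (n = 2). Mbp, a structural gene of myelin, fell from 114 ± 30.2 to 15.6 ± 6.3 CPM (n = 2).

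In edgeR's quasi-likelihood test 2906 of 16398 genes passed, 2013 higher and 893 lower, and 1922 and 866 of these changed by at least 2-fold. Sprr1b (ENSRNOG00000031144, chromosome 2, 192623244 to 192623681 in the files' coordinates, whose genome build is not given in the sources used here), a precursor of the cornified envelope with 0 counts in untreated skin, was at least 107-fold higher (adjusted p = 0.00608). S100a9 (ENSRNOG00000011483, chromosome 2, 190097554 to 190100276) rose by a log2 fold change of 9.93 ± 0.695 (SE; adjusted p = 0.00608). Krt86, a hair keratin on chromosome 7 (143122269 to 143128932), rose with a count ratio of 1340 (95% interval 241 to 53000; adjusted p = 0.0162). The hair keratin-associated proteins Krtap31-1 and Krtap1-3 were at least 32.6-fold and 19.8-fold higher, and Krtap22-2 had a count ratio of 722 (247 to 3500). Il19, a cytokine of the IL-10 family, was at least 20.5-fold higher, and Il1f10, of the IL-1 family, at least 23.8-fold. The transporter gene Abca14 was at least 16-fold higher, and the tetraspanin-like Tm4sf4 had a count ratio of 636 (114 to 25200). Without gefitinib replicate 1 the ratios of Krt86 and Krtap22-2 were 810 and 434 and the bound of Il1f10 14.4, and without gefitinib replicate 2 the bound of Krtap31-1 was 20.1. Among genes that fell, Lce1m and Wfdc21 were at least 10.5-fold and 10.2-fold lower. Olig1, a glial transcription factor (chromosome 11, 31428358 to 31430517), fell to 1 count in both gefitinib libraries together, from 88 in the untreated ones (66 and 22; adjusted p = 0.0221). Ankrd1, a stretch-responsive muscle gene, had a log2 fold change of −5.35 ± 1.05 (adjusted p = 0.0197). Also lower were Gstm3 (−5.42), the glutamate receptor gene Gria1 (−4.67), Sspo (−4.40), the neural transcription factor Pou3f3 (−4.11), Dpp6 (−3.94) and Hapln2 (−3.92).

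Of the hair list 36 of 37 members rose over all genes and 36 adjusted over the list alone, with a median log2 fold change of 4.80. Krt34 rose by 6.67, Krt72 by 5.59 and Krtap8-1 by 8.22. The list was higher than other genes by camera (adjusted p = 5.66e-26; adjusted p = 0.427 with an estimated correlation). Of 31 cell cycle genes 30 rose, and 31 adjusted over the list alone, with a median of 2.92 (camera adjusted p = 2.55e-26; 0.427 as the adjusted p with an estimated correlation). Examples are the mitotic kinase gene Cdk1 (3.02 ± 0.288, adjusted p = 0.00824), the spindle gene Nusap1 (2.80) and the survivin gene Birc5 (2.70). Of 26 cholesterol synthesis genes 10 rose, 17 adjusted over the list alone, with a median of 1.15, among them Sqle (2.62 ± 0.303), Dhcr7 (2.26), Idi1 (2.13) and Cyp51 (1.53). Camera gave an adjusted p of 5.02e-06, and an adjusted p of 0.427 with an estimated correlation.

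Of 22 epidermal differentiation genes 13 rose and 1 fell, 15 and 1 adjusted over the list alone, with a median of 2.30, or 2.18 with bounded genes at their bound. Cnfn rose by 6.46, Grhl3, a regulator of the barrier, by 3.90 and Klk7, a protease that sheds cornified cells, by 3.66, whereas Lce1m fell. Camera gave an adjusted p of 1.69e-08, and an adjusted p of 0.427 with an estimated correlation. Of 20 genes of stressed keratinocytes and antimicrobial defence 15 rose, 17 adjusted over the list alone, with a median of 3.93, or 3.18 at the bound. S100a8 rose by 6.4 ± 0.49 and Sprr1a by 4.49. Its camera adjusted p was 3.21e-19, and 0.146 was the adjusted p with an estimated correlation. Of 11 basal keratinocyte genes 4 rose, including Tp63 (1.93), Itga3 (1.41) and Krt5 (1.83), and Dst (−1.86) fell. The counts adjusted over the list alone were 4 and 1, and the median of 0.674 did not pass (camera adjusted p = 0.176).

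Inflammatory genes rose as well. Of 33 chemokine and cytokine genes 15 rose and 1, Cxcl12, fell, 20 and 2 adjusted over the list alone, with a median of 3.20, or 2.79 at the bound (camera adjusted p = 4.71e-07; adjusted p = 0.146 with an estimated correlation). Il36g, a keratinocyte alarm cytokine, rose by 3.96, the IL-1 antagonist Il1rn by 3.37 and the T cell attractant Ccl17 by 5.12. Of 8 neutrophil genes 5 rose, and 5 adjusted over the list alone, with a median of 4.23 (camera adjusted p = 1.89e-10; adjusted p = 0.181 with an estimated correlation), and Mmp8 had a count ratio of 52.4 (14.3 to 436). S100a8, S100a9, Mmp8 and Mmp9 of the neutrophil list also sit in the stressed keratinocyte or protease lists, so the calls of these lists are not independent. Of 18 matrix protease genes 5 rose and 1 fell, 5 and 3 adjusted over the list alone. The collagenase gene Mmp13 rose by 5.97 (adjusted p = 0.00811), the elastase gene Mmp12 by 5.54, Mmp9 by a count ratio of 148 (40.7 to 1230), and Plau fell by 2.13. The list itself had a median of 0.265 and did not pass (camera adjusted p = 0.195).

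The interferon list, with a median of −0.63, was lower by camera (adjusted p = 0.0376; adjusted p = 0.571 with an estimated correlation). Its median was 0.0638 with library size only, which is −0.662 relative to the median of all genes. Of its 25 members Ifit1 rose with a count ratio of 41.9 (7.25 to 1680) and Ifit2 fell by 1.76, 1 and 0 adjusted over the list alone. The call was lost without untreated replicate 2 (median −0.409, adjusted p = 0.0783), gefitinib replicate 2 (0.0687), afatinib replicate 1 (0.0549) or afatinib replicate 2 (0.0581). Of 11 class II antigen presentation genes 3 fell, and 3 adjusted over the list alone, namely Cd74 (−1.79), RT1-Da (−1.36) and RT1-Db1 (−1.32). That list had a median of −1.05 (camera adjusted p = 0.0134; adjusted p = 0.571 with an estimated correlation), and its call was lost without untreated replicate 1 (median −0.534, adjusted p = 0.101) or gefitinib replicate 2 (adjusted p = 0.0653). Its median was −1.7 without gefitinib replicate 1.

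Among tissue markers, 7 of 10 Schwann cell genes fell, 8 adjusted over the list alone, with a median of −2.0, among them the myelin genes Mbp (−2.86 ± 0.381, adjusted p = 0.0106), Prx (−2.13) and Cnp (−1.71). Camera gave an adjusted p of 1.09e-06, and an adjusted p of 0.427 with an estimated correlation. Of 13 endothelial genes 4 fell, 5 adjusted over the list alone, with a median of −1.12: the angiopoietin receptor gene Tek (−2.08), Flt1 (−1.91), the lymphatic regulator Prox1 (−2.48) and Cdh5 (−2.14). The camera adjusted p was 0.000119, and 0.571 was the adjusted p with an estimated correlation. The mean of this list was −0.644 in gefitinib replicate 1 and −2.08 in replicate 2, and its median was −2.23 and −0.675 without the one or the other. With library size only, 5 Schwann cell genes fell and no endothelial, class II or JAK-STAT gene passed the edgeR test (4, 1 and 5 at an unadjusted p under 0.05). The skeletal muscle share of the counts was lower in both gefitinib libraries (5.14% and 8.93%) than in untreated skin (20.7% and 19.1%). In edgeR 0 of 16 skeletal muscle genes passed, and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. DESeq2 called 16 and limma-voom 1. Mybpc1 stood at −2.83 (adjusted p = 0.0544), Casq1 at −2.69 and Ryr1 at −2.06. That list had a median of −2.07 and was lower by camera (adjusted p = 1.38e-06; adjusted p = 0.571 with an estimated correlation).

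Of 22 collagen and matrix genes the injury-associated Tnc rose by 2.68 and 0 fell in edgeR (1 and 0 adjusted over the list alone). In this list 13 genes had an unadjusted p under 0.05, DESeq2 called 13 and limma-voom 1. Col5a2 and Col5a1 stood at −1.77 and −2.27 (adjusted p = 0.0597 and 0.0743), and the median was −1.65 (camera adjusted p = 0.000206; adjusted p = 0.66 with an estimated correlation). The mean of the collagen list was −0.529 in gefitinib replicate 1 and −2.42 in replicate 2, and its median was −1.07 without untreated replicate 1 and −2.82 without gefitinib replicate 1. Of 17 clock genes Bhlhe41 fell by 1.95, 12 fell adjusted over the list alone, and the median was −1.09 (camera adjusted p = 0.000171; adjusted p = 0.427 with an estimated correlation). With library size only 0 clock genes passed the edgeR test, and 4 had an unadjusted p under 0.05. DESeq2 called 9 clock genes and limma-voom 0. Of 6 genes of sweat, mammary or salivary glands the simple-epithelium keratins Krt8 (4.17) and Krt18 (2.86) rose, 2 adjusted over the list alone, with a median of 2.38 (camera adjusted p = 0.0449; adjusted p = 0.427 with an estimated correlation). The call of the gland list was lost without untreated replicate 2 (adjusted p = 0.0546), afatinib replicate 1 (0.0911) or afatinib replicate 2 (0.0762).

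The signalling lists near the drug target did not pass as lists. Of 13 genes of the EGFR family and its ligands 5 rose, among them the ligands Nrg1 (5.15, adjusted p = 0.0131), Epgn (2.68) and Areg (4.11), and 2 fell, 5 and 3 adjusted over the list alone, with a median of 1.20 (camera adjusted p = 0.197). The genes that fell, Lrig1 (−1.20) and Errfi1 (−0.94), both restrain EGFR; they were chosen after their values were seen. Of 21 ERK target genes 5 rose and 2 fell, 6 and 2 adjusted over the list alone, including Ccnd1 (2.06), Epha2 (1.75), Myc (1.22) and Fos (−2.08), with a median of 0.639 (camera adjusted p = 0.31). Of 19 JAK-STAT genes 4 fell, 4 adjusted over the list alone, namely Jak1 (−1.21), Il6st (−1.52), Stat5b (−1.96) and Cish (−1.80), with a median of −0.43 (camera adjusted p = 0.0509), or 0.263 with library size only, −0.463 relative to all genes.

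Of 27 sebaceous and lipid synthesis genes 6 rose and 1 fell, 7 and 2 adjusted over the list alone, among them the fatty acid synthesis genes Acly (1.89), Fads2 (2.21) and Fasn (2.25), and the lipid droplet gene Plin5 (−2.40), with a list median of 0.147 (camera adjusted p = 0.56). Of 16 glucocorticoid response genes the metallothioneins Mt1 (2.97), Mt1m (4.05) and Mt2A (3.76), which bind metals, rose, and 3 genes including Pdk4 (−2.40) fell, 3 and 7 adjusted over the list alone. The list had a median of −0.69 and a mean of −0.000803 (camera adjusted p = 0.488). Of 19 heat shock and unfolded protein genes 1, Asns (2.79), rose and 6 fell, 1 and 8 adjusted over the list alone, including Atf3 (−3.20), Hspb1 (−2.20) and Chac1 (−2.37), with a median of −0.38 (camera adjusted p = 0.0718), or 0.288 and 3 genes lower with library size only.

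Other cell type lists did not pass by camera. T and NK cell genes had 2 of 15 higher, among them the T cell kinase gene Zap70 (count ratio 15.5, 5.09 to 76.9), 1 adjusted over the list alone, with a median of −0.63 but a mean of 0.136 and a test pointing up (adjusted p = 0.981). Mast cell genes had 2 of 9 higher, Kit (2.51) and Hdc (2.91), with a median of −0.34 but a mean of 0.389 and a test pointing up (adjusted p = 0.56). Smooth muscle and pericyte genes had 2 of 10 lower, Rgs5 (−2.19) and Lmod1 (−1.86), with a median of −0.40 (adjusted p = 0.0903), or 0.34 with library size only, −0.386 relative to all genes, where the list passed (adjusted p = 0.0349) and no member did. Adipocyte genes had 1 of 13 higher, Retn (4.08), and 1 lower, Acsl1 (−1.92), 1 and 3 adjusted over the list alone, with a median of 0.0718, a mean of 0.157 and a test pointing down (adjusted p = 0.459). Fibroblast genes had 1 of 11 higher, the retinoic acid binding gene Crabp1 (2.88), and a median of −1.19 (adjusted p = 0.105). In edgeR's test 0 members passed in the lists of B cells (median −0.74, mean 0.814, test pointing down, camera adjusted p = 0.56), macrophages (−0.34, 0.281), dendritic cells (−0.29, 0.524), eosinophils (0.614, 0.794), erythrocytes (0.864, 0.524) and melanocytes (2.65, 0.794), given as list median and camera adjusted p. In the last 6 lists 1, 2, 0, 1, 2 and 0 genes had an unadjusted p under 0.05; DESeq2 called 1 macrophage and 1 erythrocyte gene, and limma-voom 1 eosinophil gene.

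Leaving out 1 library turned the sign of several of these medians. Without gefitinib replicate 2 they were −2.15 for melanocytes, 0.194 for smooth muscle and pericytes and 0.233 for dendritic cells. Without gefitinib replicate 1 they were −1.12 for erythrocytes, −0.596 for adipocytes, −0.227 for matrix proteases and −0.145 for sebaceous genes. Without untreated replicate 1 they were 0.735 for T and NK cells and 0.0721 for dendritic cells, and without untreated replicate 2 0.129 for mast cells, −0.191 for adipocytes and −0.0278 for matrix proteases. The adipocyte median was −0.0812 and −0.154 without afatinib replicate 1 or 2. None of these lists passed then either. The melanocyte list mean was −1.32 in gefitinib replicate 1 and 2.96 in replicate 2, and the smooth muscle mean 0.211 and −1.56, so the replicates went opposite ways in both lists.

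Without untreated replicate 1 or 2, 10 and 0 genes passed, without gefitinib replicate 1 or 2, 808 and 371, and without afatinib replicate 1 or 2, 5159 and 5320. Of 100 named genes that passed, 100 lost the call without untreated replicate 2, 98 without untreated replicate 1, and 50 and 61 without gefitinib replicate 1 or 2. DESeq2 called 4588 genes, the fit of only the groups compared 5286, no low-count filter 4550, deposited FPKM with no filter 988, and the fit with the muscle list as a covariate 10. That covariate was lower in every treated library than in both untreated ones, so its low count does not show muscle content to be the cause. With library size only, 3071 genes were higher and 191 lower (94.1% higher, against 69.3%). The median of all genes then stood at 0.726 in this comparison, 0.706 for afatinib and 0.716 for the mean of both. Keratins, Krtap, Sprr, S100, Stfa, RT1, metallothionein and globin genes have near-identical copies, and how reads that match several were counted is not given in the sources used here, so their single values are uncertain.

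Afatinib against untreated asks the same of skin with an afatinib rash. S100a9 rose from 0.491 ± 0.283 to 814 ± 143 CPM (n = 2), and Il1b, the gene of the inflammatory cytokine IL-1 beta, from 0.769 ± 0.183 to 38.6 ± 20.6 CPM (n = 2). Tgm1 rose to 31.4 ± 6.19 CPM and the hair keratin gene Krt31 to 169 ± 175 CPM (n = 2), with a wide spread between the libraries. Mybph, a myosin-binding muscle gene, fell from 653 ± 18.6 to 51.2 ± 3.77 CPM, and Mbp to 19.0 ± 4.12 CPM (n = 2). The plot of single genes shows the 6 libraries.

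**Figure D2:**
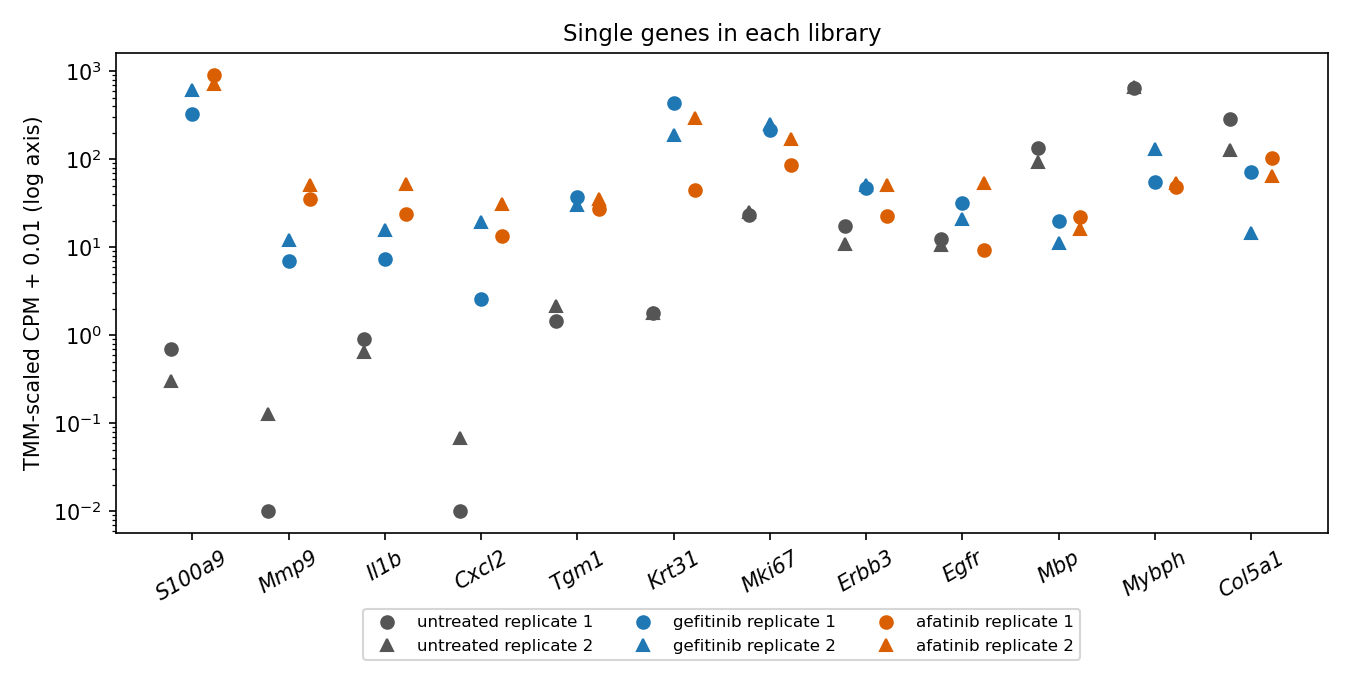
TMM-scaled CPM plus 0.01 on a log axis for 12 genes in each library; colours mark the groups and shapes the replicates. S100a9 averages 0.491 CPM in untreated skin, 476 with gefitinib and 814 with afatinib, and Mbp 114, 15.6 and 19.0.

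In the edgeR test 652 genes passed, 591 higher and 61 lower. Sprr1b was at least 58.6-fold higher (adjusted p = 0.00563) and S100a9 had a log2 fold change of 10.71 ± 0.712 (adjusted p = 0.00354). The gelatinase gene Mmp9 had a count ratio of 717 (198 to 5920; adjusted p = 0.00519), the neutrophil attractant gene Cxcl2 one of 775 (139 to 30600; adjusted p = 0.0331) and Krt86 one of 1020 (182 to 40200; adjusted p = 0.0412). Tmprss11g, a membrane protease gene, was at least 33.4-fold higher, Calca, which encodes calcitonin and the neuropeptide CGRP, at least 26.1-fold. Il19 was at least 14.8-fold higher and the peroxidase gene Lpo at least 14.1-fold. Several of these values rest on afatinib replicate 2. Without it the ratios of Krt86 and Cxcl2 were 113 and 428, and the bounds of Calca and Lpo 6.12 and 6.46. Krt86 had 55 counts in afatinib replicate 1 and 1272 in replicate 2, Cxcl2 208 and 804, and Calca 18 and 228. Without afatinib replicate 1 the values were 1550 for Krt86, 46 for Calca and 21.8 for Lpo. Stfa3, a cysteine protease inhibitor gene, rose by 8.74 ± 0.71. Olig1 was at least 18.8-fold lower (adjusted p = 0.0424), a bound that leans on untreated replicate 1, with 66 counts against 22 in replicate 2. Mybph (chromosome 13, 51034256 to 51041902) fell by 3.67 on the log2 scale (SE 0.481, adjusted p = 0.0257) and Pdk4, which spares glucose, by 3.70 (SE 0.599). Fbxo32, a muscle ubiquitin ligase gene, fell by 3.02, Ucp3 by 2.85, the tight junction gene Cldn19 by 3.17, Kcnq1 by 2.83, Fuom by 5.76 and Pcgf1 by 4.46.

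Of the 20 stressed keratinocyte genes 15 rose, 18 adjusted over the list alone, with a median of 4.37, or 3.63 at the bound (camera adjusted p = 8.89e-39; adjusted p = 0.0446 with an estimated correlation). Of the 33 chemokine and cytokine genes 12 rose, 21 adjusted over the list alone, among them Il36g (4.97), Il1b (5.65 ± 0.627) and Il24 (4.45), with a median of 3.27, or 2.85 at the bound (camera adjusted p = 3.41e-15; adjusted p = 0.0446 with an estimated correlation). These were the 2 lists called with an estimated correlation. Of 8 neutrophil genes 5 rose, 7 adjusted over the list alone, with the granulocyte growth factor receptor gene Csf3r at 4.38 and a median of 4.83 (camera adjusted p = 4.43e-22; adjusted p = 0.0657 with an estimated correlation). Of 18 matrix protease genes 5 rose, 6 adjusted over the list alone, with Mmp13 at 8.39, Mmp12 at 6.93 and Mmp3 at 4.78 and a median of 0.832 (camera adjusted p = 3.08e-06; adjusted p = 0.33 with an estimated correlation). Limma-voom called 7 stressed keratinocyte, 1 chemokine or cytokine, 3 neutrophil and 3 matrix protease genes, and DESeq2 called 17, 21, 7 and 6. The protease median was 1.45 without untreated replicate 1, 1.46 without afatinib replicate 1 and 0.175 without afatinib replicate 2, and the neutrophil median 7.75 without untreated replicate 1.

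Of 37 hair genes 18 rose, 37 adjusted over the list alone, with a median of 4.05, Krt34 at 5.56 and Krtap8-1 at 7.06 (camera adjusted p = 9.73e-28; adjusted p = 0.33 with an estimated correlation). Of 31 cell cycle genes 19 rose, 30 adjusted over the list alone, with a median of 2.27, Cdk1 at 2.27 ± 0.281, Plk1 at 2.64 and Top2a at 2.60 (camera adjusted p = 2.84e-25; adjusted p = 0.33 with an estimated correlation). Of 22 epidermal differentiation genes 7 rose, 16 rose and 2 fell adjusted over the list alone, with a median of 2.10 and Cnfn at 6.36 (camera adjusted p = 2.18e-11; adjusted p = 0.33 with an estimated correlation). Of 26 cholesterol synthesis genes 5 rose, 15 adjusted over the list alone, with a median of 0.987 and Sqle at 2.31 (camera adjusted p = 1.14e-06; adjusted p = 0.33 with an estimated correlation). The basal keratinocyte list had 2 of 11 higher, 6 adjusted over the list alone, among them the laminin gene Lamb3 (2.22), with a median of 1.25 (camera adjusted p = 0.00173; adjusted p = 0.546 with an estimated correlation). Limma-voom called 0 hair, 0 cell cycle, 2 epidermal differentiation, 0 cholesterol synthesis, 0 basal keratinocyte and 0 EGFR family genes. DESeq2 called 34, 29, 16, 10, 6 and 6 in these lists. The EGFR family list had 3 of 13 higher, Nrg1 (5.39), Areg (4.83) and Epgn (2.55), 5 higher and 1 lower adjusted over the list alone, with a median of 1.45 (camera adjusted p = 0.0222; adjusted p = 0.33 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.177). Without afatinib replicate 2 the medians were 2.68 for hair, 1.47 for cell cycle, 0.795 for basal keratinocyte and 0.629 for EGFR family genes, each still past camera.

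Schwann cell genes were again lower: 3 of 10 fell, 8 adjusted over the list alone, among them Mbp (−2.59 ± 0.377) and Prx (−1.68), with a median of −1.80 (camera adjusted p = 8.41e-10; adjusted p = 0.252 with an estimated correlation). The skeletal muscle list had a median of −1.33 (camera adjusted p = 1.34e-06; adjusted p = 0.544 with an estimated correlation) with 0 members past the edgeR test, 1 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. The muscle share was 16.1% in afatinib replicate 1 and 5.65% in replicate 2. Of the Schwann cell genes limma-voom called 0 and DESeq2 7. The clock list had a median of −0.58 with Per1 lower (−1.26), 1 adjusted over the list alone (camera adjusted p = 0.00129; adjusted p = 0.413 with an estimated correlation). With library size only 0 clock genes passed the edgeR test and 0 had an unadjusted p under 0.05, while DESeq2 called 2. The heat shock list had a median of −0.46, 1 and 5 genes adjusted over the list alone, and Asns higher (2.73) (camera adjusted p = 0.00343; adjusted p = 0.33 with an estimated correlation). Its median was 0.0979 with library size only, −0.608 relative to all genes. The glucocorticoid list had a median of −0.91, 4 higher and 8 lower adjusted over the list alone, with Mt1 (2.17) and Mt2A (3.32) higher and Cebpd (−1.59) lower (camera adjusted p = 0.0165; adjusted p = 0.33 with an estimated correlation), a call lost without afatinib replicate 1 (adjusted p = 0.182). The collagen list had a median of −0.84 with Tnc higher (3.42), 1 adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.773 with an estimated correlation), a call lost without untreated replicate 1 (median −0.462, adjusted p = 0.293), afatinib replicate 1 (0.0758) or afatinib replicate 2 (0.101). Without afatinib replicate 1 the medians were −2.74 for muscle, −0.962 for clock and −0.786 for heat shock genes, and without afatinib replicate 2 −0.803 for muscle and −0.257 for clock genes. The clock median was −0.264 without untreated replicate 2.

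The remaining 18 lists did not pass by camera. Single members that rose were Ccnd1 (1.91) of the ERK targets, Ifit1 (count ratio 229, 40.8 to 9070) of the interferon list, Zap70 (count ratio 19.7, 6.48 to 97.4) of the T and NK cell list, Kit (1.48) and Hdc (3.36) of the mast cell list, Retn (5.22) of the adipocyte list, Crabp1 (2.17) of the fibroblast list and Krt8 (3.27) of the gland list, and Plin5 (−2.42) of the sebaceous list fell. The T and NK cell and the mast cell lists had the smallest camera p-values among these lists (adjusted p = 0.0577 each, medians 0.675 and 0.66). Medians were above 0 while the test pointed down for B cells (0.0429), smooth muscle and pericytes (0.702) and melanocytes (1.37). Without afatinib replicate 1 the melanocyte median was −3.29 and the B cell median −0.474, and without untreated replicate 2 the B cell median was −0.254.

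Without untreated replicate 1 or 2, 1 and 0 genes passed, without gefitinib replicate 1 or 2, 69 and 65, and without afatinib replicate 1 or 2, 3653 and 134. Of 67 named genes that passed, 67 lost the call without either untreated library, 44 without either gefitinib library and 38 without afatinib replicate 2. Limma-voom called 34 genes, DESeq2 1955, the fit of only the groups compared 51, no low-count filter 2083, deposited FPKM 22 to 403, library size only 1281 (97.6% higher, against 90.6%) and the muscle list covariate 35.

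The mean of both inhibitors against untreated asks how skin with an EGFR inhibitor rash differs on average; a gene can pass it through a change with 1 inhibitor. Of the genes that passed, 626 were called with each inhibitor, 1785 with gefitinib alone, 25 with afatinib alone and 182 with neither. Sprr1b was at least 82.9-fold higher (adjusted p = 0.00511) and S100a9 rose by 10.32 ± 0.692 (adjusted p = 0.00472). Hair genes rose, among them Krt86 (count ratio 1190, 214 to 47100), Krt83 (549, 152 to 4530), Krtap22-2 (549, 188 to 2660) and Krtap1-3 (at least 23.6-fold higher). The cytokine genes Il1f10 and Il19 were at least 21.1-fold and 17.7-fold higher, Tmprss11g at least 23.2-fold and Calca at least 20.6-fold. Libraries differed widely in the hair genes: gefitinib replicates 1 and 2 and afatinib replicates 1 and 2 had 1465, 585, 55 and 1272 counts of Krt86 and 1138, 174, 32 and 1766 of Krt83. Without afatinib replicate 2 the ratio of Krt83 was 334, and the bounds of Krtap1-3 and Calca 14.4 and 12.1. Among genes that were lower were Ankrd1 (−4.76 ± 0.767, adjusted p = 0.0148), Mybph (−3.24) and Klhl34 (−3.62). Olig1 and Wfdc21 passed too, but no fold is given for them, since Olig1 had 0 counts with afatinib and Wfdc21 0 with gefitinib. Also lower were Lce1m, at least 9.38-fold, and Gria1 (−3.72), Gstm3 (−3.64), Fuom (−3.46) and Sspo (−3.20).

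In this comparison 2618 genes passed the edgeR test, 1810 higher and 808 lower, or 3126 and 225 with library size only. Of the lists, 9 were higher by camera: stressed keratinocyte (17 of 20 rose; adjusted p = 1.34e-25), hair (35 of 37; 1.34e-25), cell cycle (29 of 31; 1.63e-25), neutrophil (5 of 8; 2.48e-14), chemokines (17 of 33; 8.84e-10), epidermal differentiation (13 of 22; 2.83e-09), cholesterol synthesis (10 of 26; 1.82e-06), matrix proteases (5 of 18; 0.00982) and basal keratinocyte (5 of 11; 0.0335). In 3 of these lists members also fell: 2 epidermal differentiation, 1 protease and 1 basal keratinocyte gene. The lower lists were Schwann cell (8 of 10 fell; camera adjusted p = 2.22e-09), skeletal muscle (0 of 16; 1.55e-07), clock (2 of 17; 0.000237), collagens (0 of 22, and 1 rose; 0.000998), endothelial (4 of 13; 0.00164), heat shock (6 of 19, and 1 rose; 0.0129) and class II (0 of 11; 0.0355). These counts are those of edgeR. At an unadjusted p under 0.05 were 7 skeletal muscle, 10 collagen and 5 class II genes. DESeq2 called 15, 11 and 2 in these lists and limma-voom 0, 1 and 0. With library size only 0 clock and 0 endothelial genes passed the edgeR test (0 and 1 at an unadjusted p under 0.05), while DESeq2 called 7 and 5. With an estimated correlation 0 lists passed by camera, with the smallest adjusted p = 0.0872 for the stressed keratinocyte and chemokine lists, and fry called 5. The basal keratinocyte call was lost without untreated replicate 2 (adjusted p = 0.16), and the class II call without untreated replicate 1 (0.311), gefitinib replicate 2 (0.0755), afatinib replicate 1 (0.0662) or afatinib replicate 2 (0.076).

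Without untreated replicate 1 or 2, 20 and 3 genes passed, without gefitinib replicate 1 or 2, 1245 and 926, and without afatinib replicate 1, 5809. Of 97 named genes that passed, 97 lost the call without untreated replicate 2, 91 without untreated replicate 1, 24 and 29 without gefitinib replicate 1 or 2, and 1 without afatinib replicate 2. DESeq2 called 4156 genes, no low-count filter 4200, deposited FPKM with no filter 730 and the muscle list covariate 40.

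Of the genes called in both inhibitor comparisons, 575 were higher in both, 51 lower in both and 0 went opposite ways. They include Sprr1b, S100a9, Tgm1, Nrg1, Areg, Il36g, Mmp13, Cdk1 and Sqle among those higher, and Mbp and Prx of peripheral myelin among those lower. The overlap of independent lists of these sizes would be 72.55 and 3.322 genes, with 39.67 opposite, and simulations without any change gave 0.05 and 0. With no gene changed little can be called, so the simulated overlap does not show what shared controls add to lists of these sizes. The log2 fold changes correlated across genes at r = 0.907, against 0.513 in simulations, with a covariance of 1.852 against 0.158. Both comparisons use the same untreated libraries, which are too few to split, so the excess over independent lists includes what those libraries share. Without untreated replicate 1 or 2 the overlap was 1 and 0, without gefitinib replicate 1 or 2 57 and 56, and without afatinib replicate 1 or 2 3137 and 129. It was 1813 with DESeq2, 33 with limma-voom, 45 with only the groups compared, 1225 with library size only, 1914 with no low-count filter, 19 to 388 with deposited FPKM and 8 with the muscle list covariate.

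**Figure D3:**
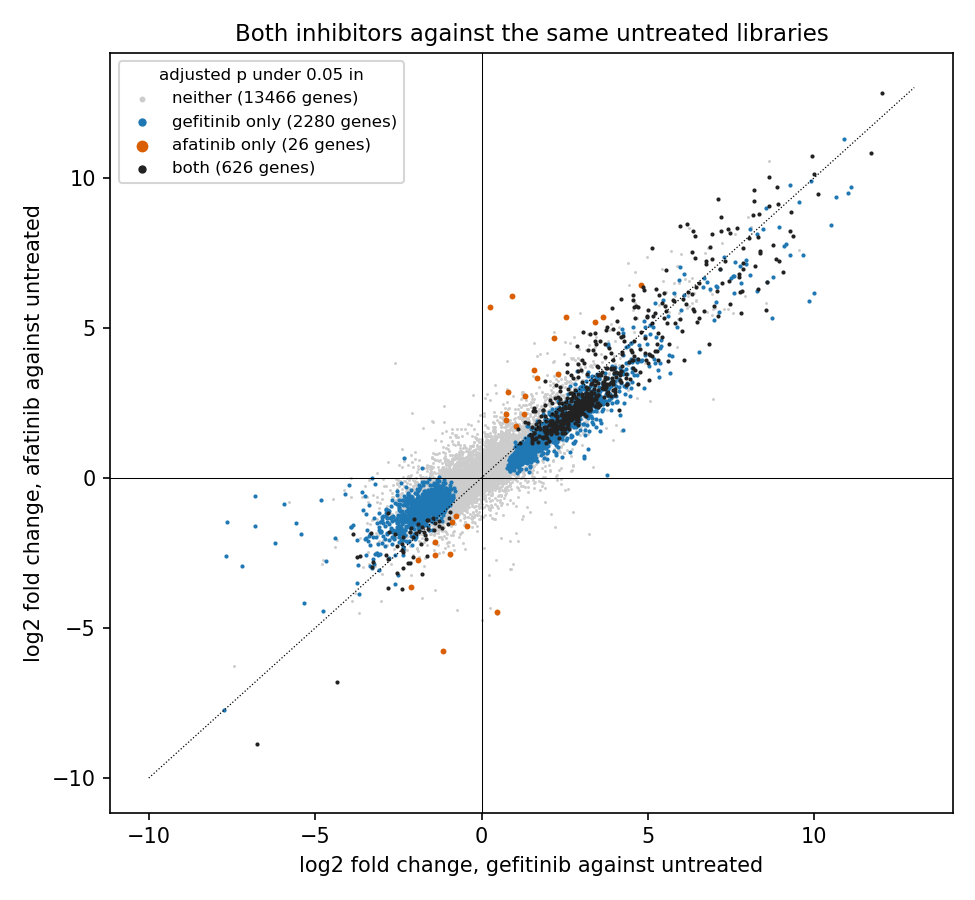
Log2 fold change against untreated with gefitinib (x axis) and afatinib (y axis) for the 16398 tested genes, coloured by the comparison in which they passed the test; the dotted line marks equal changes. The 626 genes called in both lie in the upper right and lower left, and 2280 passed with gefitinib alone and 26 with afatinib alone.

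Afatinib against gefitinib compares the related compounds directly, at doses of 30 and 80 mg/kg. Matrix protease and inflammatory genes had higher values with afatinib, as for Mmp13 (55.0 ± 17 against 10.2 ± 4.33 CPM, n = 2) and Mmp9 (43.2 ± 11.5 against 9.49 ± 3.6 CPM, n = 2), and hair and cell cycle genes lower values, as for Mki67 (130 ± 60.3 against 236 ± 24.5 CPM, n = 2). The lower values rest on afatinib replicate 1, where the hair and cell cycle list means were 2.95 and 1.49. They were 5.15 and 2.53 in replicate 2, and 5.37 and 2.67, and 4.78 and 2.68, in the gefitinib libraries. Without afatinib replicate 1 the median difference was −0.177 for hair (adjusted p = 0.772) and −0.126 for cell cycle genes (adjusted p = 0.0334). Without afatinib replicate 2 the chemokine difference was 0.231 (adjusted p = 0.397). None of these single differences passed the test. The log2 difference was 2.43 ± 0.382 for Mmp13 (adjusted p = 0.711), and with adjusted p = 0.787 it was 2.19 for Mmp9, 1.73 for Il1b, 1.82 for the prostaglandin synthase gene Ptgs2, 1.64 for the stress keratin gene Krt16, −1.72 for Krt72, −0.87 for Mki67 and −0.75 for Cdk1.

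In edgeR's quasi-likelihood test 0 genes passed, with 946 at an unadjusted p under 0.05; DESeq2 called 28, limma-voom 0 and the deposited FPKM with limma 0. The smallest adjusted p was that of Mrpl53, a mitochondrial ribosomal protein gene (chromosome 4, 113942041 to 113942674; log2 difference 5.46 ± 0.547, adjusted p = 0.269). Genes filled in by unadjusted p, which did not pass, were Hprt1 (5.14), Mff (3.38), G0s2 (2.08) and Cytl1 (1.66) on the higher side and Pcgf1 (−4.91), Fuom (−4.60), Krtap31-1 (−3.81), Krtap1-5 (−2.96) and Tm4sf4 (−2.20) on the lower side. The 95% interval of the difference lay within 2-fold for 5054 of 16398 genes (30.8%) and within 4-fold for 12441 (75.9%); among the 626 genes called in both comparisons it did so for 59 and 478. A difference of the compounds larger than 2-fold is thus not excluded for most genes.

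Lists showed differences that single genes did not: 23 of 34 passed by camera, none with an estimated correlation (0, smallest adjusted p = 0.337) and 0 by fry, and each is given among the additional observations. Of the 11 that did not pass, the EGFR family had a median of 0.249 (camera adjusted p = 0.269), ERK targets 0.125 (0.522), epidermal differentiation −0.21 (0.157), sebaceous genes 0.282 (0.157), cholesterol synthesis −0.14 (0.0807), heat shock −0.076 (0.514), Schwann cell 0.288 (0.514), melanocyte −0.95 (0.188), eosinophil −0.49 (0.465) and erythrocyte −0.16 (0.995). B cell genes had a median of 0.78 and a mean of −0.33 (camera adjusted p = 0.522). Signs turned without afatinib replicate 1 for epidermal differentiation (0.14), cholesterol synthesis (0.0161), Schwann cell (−0.128) and B cell genes (−1.05). They turned without afatinib replicate 2 for ERK targets (−0.0231), sebaceous (−0.0565), heat shock (0.0677), erythrocyte (0.0719) and melanocyte genes (0.0426). Without gefitinib replicate 2 the ERK median was −0.148 and the melanocyte median 3.69 (adjusted p = 0.0135), and without gefitinib replicate 1 the erythrocyte median was 1.17 (adjusted p = 0.0289).

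The drug targets were examined in each comparison. Erbb3, a kinase-impaired partner of EGFR (chromosome 7, 2989340 to 3010350), rose with gefitinib by 1.79 ± 0.421 (adjusted p = 0.0316), from 14.3 ± 4.73 to 49.2 ± 2.45 CPM (n = 2). With afatinib it stood at 37.1 ± 20 CPM and 1.38 ± 0.417 (adjusted p = 0.111). Egfr itself (chromosome 14, 99919485 to 100098796) had 11.6 ± 1.45 CPM in untreated skin, 26.5 ± 7.59 with gefitinib and 31.4 ± 31.3 with afatinib (n = 2), with log2 fold changes of 1.20 (adjusted p = 0.247) and 1.45 (adjusted p = 0.279). Erbb2 (chromosome 10, 86367596 to 86391728) had 4.95 ± 1.72, 13.9 ± 0.442 and 14.5 ± 13.1 CPM (n = 2), with log2 fold changes of 1.48 (adjusted p = 0.144) and 1.55 (adjusted p = 0.223). Erbb4 had 0 to 3 counts in each library and was below the filter. Between the compounds the log2 difference was −0.41 for Erbb3 (95% interval −1.357 to 0.546), 0.25 for Egfr (−1.349 to 1.848) and 0.07 for Erbb2 (−1.407 to 1.55).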

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

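The tests of the hair, cell cycle and muscle gene explanations and the test of raw counts were chosen after the results were seen, and for the genes 8-fold apart the reading of counts against their interval was set after. What drew attention to the lists here is a difference between the inhibitors, tested directly with camera, with single genes not past the test.

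Lower with afatinib than with gefitinib, as median log2 difference and camera adjusted p, were the lists of cell cycle (−0.548, 2.05e-10), hair (−0.807, 5.11e-09), gland (−1.13, 0.00195) and glucocorticoid response genes (−0.416, 0.00683). Higher were interferon response (0.896, 9.42e-10), matrix proteases (0.708, 3.19e-09), endothelial cell (0.848, 2.29e-07), collagens (0.679, 4.87e-05), smooth muscle and pericyte (0.889, 0.000301), neutrophil (1.01, 0.000385), T and NK cell (1.17, 0.000957) and macrophage genes (0.701, 0.000957). So were JAK-STAT (0.428, 0.0018), class II antigen presentation (0.682, 0.00238), stressed keratinocyte (0.661, 0.00258), adipocyte (1.03, 0.00628), clock (0.541, 0.00877), skeletal muscle (0.687, 0.0105), chemokine (0.479, 0.0178), fibroblast (0.647, 0.0188), basal keratinocyte (0.334, 0.0293), dendritic cell (0.476, 0.0364) and mast cell genes (0.846, 0.0425). With an estimated correlation the adjusted p lay between 0.337 and 0.646 for all 23 of these lists.

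Single libraries decide several of these differences. Without afatinib replicate 1, which had a muscle share of 16.1%, the hair difference was −0.177 (adjusted p = 0.772), the skeletal muscle difference −0.749 (0.00302, past the test in the opposite direction), clock 0.248 (0.66), macrophage 0.0393 (0.607), mast cell 0.473 (0.66), class II 0.644 (0.0588) and fibroblast −0.0265 (0.678). Without gefitinib replicate 2, which had a collagen share of 0.227%, collagens stood at 0.0609 (0.789), endothelial genes at 0.183 (0.0682), smooth muscle at 0.444 (0.211), fibroblasts at 0.046 (0.566), JAK-STAT at 0.137 (0.304), class II at 0.536 (0.181), dendritic cells at 0.281 (0.404), macrophages at 0.452 (0.0551), basal keratinocytes at 0.342 (0.0802), mast cells at 0.734 (0.0693) and glucocorticoid response at −0.0564 (0.0667). Without afatinib replicate 2, chemokines stood at 0.231 (0.397), stressed keratinocyte genes at 0.36 (0.179), neutrophil genes at 0.913 (0.0738), adipocytes at 0.0253 (0.792), basal keratinocytes at −0.0271 (0.923), JAK-STAT at 0.301 (0.0661), dendritic cells at 0.608 (0.197), glands at −1.5 (0.0637) and glucocorticoid response at −0.546 (0.0661). Without gefitinib replicate 1, skeletal muscle stood at 0.316 (0.708), clock at 0.375 (0.22), mast cells at 0.874 (0.154) and basal keratinocytes at 0.347 (0.159).

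With other libraries left out, differences kept their call but moved by over 1.5 times. Without afatinib replicate 1 they were −0.126 for cell cycle, 0.572 for interferon, 0.354 for collagens, −0.142 for glucocorticoid response, 0.563 for T and NK cell and 0.698 for basal keratinocyte genes. Without afatinib replicate 2 they were −2.15 for hair, −1.23 for cell cycle, 0.471 for proteases, 1.35 for skeletal muscle, 0.495 for smooth muscle and 1.12 for fibroblast genes. Without gefitinib replicate 1 they were −0.441 for hair, 1.15 for proteases, 1.94 for collagens, 1.9 for endothelial, 2.42 for smooth muscle, 1.67 for fibroblast, 0.832 for JAK-STAT, 1.35 for class II, 0.76 for dendritic cell, −0.696 for glucocorticoid response and −0.701 for gland genes. Without gefitinib replicate 2 they were 0.382 for proteases and 1.29 for skeletal muscle.

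The hair and cell cycle lists were higher with both inhibitors by camera at the preset correlation, calls that were lost with an estimated correlation. A smaller share of skeletal muscle in the treated pieces would raise markers of the rest of the skin alike. In the mean of both inhibitors, however, the hair list rose by 3.26 more than the basal keratinocyte list (95% bootstrap interval over genes 2.47 to 4.71). The cell cycle list rose by 1.25 more (0.853 to 2.54). Both lists were picked after their rise was seen, so a difference above 0 follows largely from that choice and does not decide. The intervals cover genes that may move together, not libraries. In the treated libraries the hair list means were 2.95 to 5.37 and the basal keratinocyte means 0.637 to 1.43. The untreated values were −0.273 and 0.273 for hair and 0.256 and −0.256 for basal keratinocyte genes. For the hair list the gap exceeds the untreated spread in every treated library, which argues against a smaller muscle share as its whole cause. For cell cycle genes that share stays open. Hair cycle stage unrelated to the drugs could give the same pattern: 0 untreated libraries reached the lowest hair share of a treated library, which a drug effect gives as well. With 2 libraries per group, hair cycle stage and drug cannot be told apart, and the drug effect stays a hypothesis.

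The muscle genes Mybph, Fbxo32, Ucp3, Pdk4 and Ankrd1 were lower with both inhibitors. If a smaller share of skeletal muscle were the cause, they would fall as much as the muscle list; their median change minus the mean of the list was −0.397 and −0.389 with gefitinib and −2.6 and −0.883 with afatinib, against −0.462 and 0.462 in untreated skin. These genes were named for falling most, 4 of them with afatinib, so values below the list follow from that choice and decide nothing. The gefitinib values lie within the untreated range, and both afatinib values lie below it. In afatinib replicate 1 these genes had a median change of −3.21, while the mean of the muscle list was −0.606. On genes chosen for their fall such a gap does not decide, so a smaller muscle share stays open with both inhibitors. Feeding state or handling of the animals could also lower these genes: 2 treated libraries, both gefitinib, lie above the lower untreated value, by less than the spread of the untreated pair, on the same chosen genes, so it stays open too. An effect of the drugs on muscle was not tested apart from these.

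At least 8-fold apart from the 4 other libraries in both afatinib libraries were 3 genes, Mrpl53 and Hprt1 (higher) and Pcgf1 (lower); Mrpl53 and Pcgf1 are neighbours on chromosome 4. Variants or other differences between single animals that are unrelated to the drugs may give such genes: the highest count among the 12 pairs of libraries from different groups was 2, and a count of 3 has a 95% interval of 0.619 to 8.77, which holds 2. The untreated pair had 109 such genes and the gefitinib pair 0. Raw counts were set beside scaling between libraries as the cause. The genes were picked for gaps of at least 8-fold, so a raw gap wider than the scaling follows largely from that choice and is no separate evidence. The nearest raw counts of the afatinib pair and the other libraries differed by 26.6-fold for Mrpl53 (95% interval 18.3 to 39.9), 14.9-fold for Hprt1 (8.7 to 27.8) and 7.67-fold for Pcgf1 (3.27 to 22), whereas scaled library sizes differed by at most 1.79-fold. With library size only the count was again 3 against 2, with Mrpl53 and Hprt1 kept and Fuom in place of Pcgf1. Differences between single animals and an effect of afatinib stay open.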

How the results depend on the processing

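The muscle list covariate was chosen after the data were seen, and the other alternatives were planned. The covariate overlaps with treatment, so a fall in calls with it does not show that muscle content causes the changes. The replicate number is not a pairing in the labels, and deviations of equal numbers correlated across genes at 0.0331, 0.0374 and −0.174, so the block is given once: 369 genes for afatinib and 354 in both. With 1 library left in a group, it was assumed to vary like the other groups. The causes of the changes below were not tested, except that a looser threshold passes more genes.

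For gefitinib (2906 genes) no filter gave 4550, DESeq2 4588, only the groups compared 5286, FPKM with no filter 988, a threshold of 0.1 4983 and the muscle covariate 10; leaving out 1 library gave 0 to 5320. For afatinib (652) the values were 2083, 1955, 51, 22, 1597 and 35, with library size only 1281, limma-voom 34, FPKM plus 1 253 and FPKM plus 0.1 403, and 0 to 3653 without 1 library. For the mean (2618) no filter gave 4200, DESeq2 4156, FPKM with no filter 730, a threshold of 0.1 4574 and the covariate 40, and leaving out 1 library 3 to 5809. For afatinib against gefitinib (0 by edgeR, 946 at an unadjusted p under 0.05) library size only gave 1, no filter 28, DESeq2 28 and leaving out 1 library 0 to 3. The overlap (626) was 1225 with library size only, 1914 with no filter, 1813 with DESeq2, 33 with limma-voom, 45 with only the groups compared, 238, 388 and 19 with FPKM plus 1, plus 0.1 and no filter, 1527 at a threshold of 0.1, 8 with the covariate and 0 to 3137 without 1 library.

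Lists called fell from 15 (gefitinib), 16 (afatinib), 16 (mean) and 23 (afatinib against gefitinib) to 0, 2, 0 and 0 by camera with an estimated correlation and to 5, 3, 5 and 0 by fry. Leaving out 1 library gave 14 to 19, 15 to 20, 15 to 18 and 14 to 23. With the muscle list covariate 15, 16, 15 and 22 lists were called by camera at the preset correlation. In that fit the melanocyte list, not called before, stood at 4.88 (afatinib) and 7.29 (mean), the muscle list at −0.173 (afatinib against gefitinib), and Olig1 at 0.57 with gefitinib. In afatinib against gefitinib, leaving out 1 library gave medians of −0.0271 (without afatinib replicate 2) to 0.698 for basal keratinocytes, 0.0609 (without gefitinib replicate 2) to 1.94 for collagens, −0.749 (without afatinib replicate 1) to 1.35 for skeletal muscle, −0.624 to 1.17 (without gefitinib replicate 1) for erythrocytes, −5.9 to 3.69 (without gefitinib replicate 2) for melanocytes and −0.0265 to 1.67 for fibroblasts, with 0.046 without gefitinib replicate 2. With size factors of the DESeq2 kind, the CPM filter, robust dispersions or a 2-fold minimum, the gene counts were 2788 to 2985 for gefitinib and 567 to 676 for afatinib. Named genes were not scored with robust dispersions, FPKM plus 0.1, FPKM with no filter or other thresholds. Over the remaining alternatives, values of called named genes kept direction and call in 1137 cases for gefitinib, 610 for afatinib and 1077 for the mean. They kept the direction but lost the call in 445, 458 and 368. Lists were scored only with an estimated correlation, fry, size factors of the DESeq2 kind, the CPM filter, the block, the muscle covariate and each library left out. For called lists the numbers were 142, 155 and 153 against 38, 37 and 39, and for afatinib against gefitinib 195 against 76. The directions compared here are those of the set test, which can differ from the sign of a median. In simulated data of this depth and size, with 200 genes changed, 2-fold changes were recovered in 0.938% to 3.75% of genes. More genes than that passed against untreated in the data, so these rates may not carry over. Genes that did not pass may still differ by 2-fold.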

Other observations

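The protein family tests in this part were chosen after the data were seen. In skin with a gefitinib rash, of 20 genes with the high-sulfur B2 domain of hair keratin-associated proteins 18 were higher, against 12.2% of all genes with a family (adjusted p = 2.39e-12, one-sided Fisher's exact test over 946 families), and 8 of 8 genes of the PMG family, also keratin-associated proteins, were higher (adjusted p = 1e-05). Of 10 genes of the MCM2/3/5 family, which form the replication helicase, 9 rose (adjusted p = 1e-05), and of 37 kinesin motor genes 16 rose (adjusted p = 0.000249). Of 12 S-100 calcium-binding genes 8 rose (adjusted p = 0.00104), of 11 cystatin genes, inhibitors of cysteine proteases, 8 (adjusted p = 0.000542), and of 7 genes of the IL-1 and IL-18 family 5 (adjusted p = 0.0272). Of 9 genes with the N-terminal domain of myosin heavy chains 6 fell, against 5.84% of all (adjusted p = 0.00267). The skeletal muscle share of the counts moved with them, from 20.7% and 19.1% in untreated skin to 5.14% and 8.93% with gefitinib. Members of these families resemble each other in sequence, so their reads are not independent.

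With afatinib, 18 of 59 intermediate filament genes, which include the keratins, rose, against 3.72% of all (adjusted p = 2.05e-09), 9 of 20 high-sulfur B2 genes (adjusted p = 7e-06) and 10 of 37 kinesin motor genes (adjusted p = 0.000206). Of 9 genes with the N-terminal domain of myosin heavy chains 3 fell, against 0.399% of all (adjusted p = 0.0047), where the muscle share was 16.1% and 5.65%. Also higher were 6 of 11 cystatin genes (adjusted p = 0.00024), 6 of 12 S-100 genes (adjusted p = 0.000372), 7 of 27 serpin genes, most of them protease inhibitors (adjusted p = 0.00415), and 4 of 7 genes of the IL-1 and IL-18 family (adjusted p = 0.00478). Afatinib replicate 1 lay lower than the other treated libraries in the hair list (2.95, against 4.78 to 5.37) and the cell cycle list (1.49, against 2.53 to 2.68). In the neutrophil list it stood at 4.89, between the gefitinib libraries (4.08 and 4.38) and afatinib replicate 2 (5.34). The pigment gene Pmel had 1773 counts in gefitinib replicate 2 and 575 in afatinib replicate 1, against 38 to 157 in the other libraries. Fcrla, a B cell gene, had 442 counts in gefitinib replicate 1 and 0 to 11 in the others.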
